A study of Homo sapiens with 16 samples.

How the data were processed

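Expression in the ovarian carcinoma line SKOV-3 was measured on 16 Affymetrix arrays, 4 for each of Flag vector, Flag-Evi1, control siRNA and Evi1 siRNA, with RNA taken 65 h after transfection. Per the labels, biotinylated single-stranded cDNA was hybridised, each array in 1 colour, and the replicates of a group were cells of passages 8, 9, 10 and 11. The authors deposited 1 table of log2 signals per probe set, processed with Partek 6.4 per the submitters' processing notes. The normalization method is not given in the sources used here. The values have the range of log2 signals: the medians lay between 6.65 and 6.78, and the array columns were similar but not identical in distribution. No scanner files were used here, so background correction and probe summary could not be redone.

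The table held 28869 probe sets. The platform annotation named 1 gene for 19311 of them, several for 1751 and none for 7807, and symbols were brought up to date through their gene identifiers. The 21062 probe sets with at least 1 gene were tested. The 19311 named 18378 distinct genes, 685 of them through more than 1 probe set. Positions were taken from GRCh38.p14. No pair of arrays was a copy of another, the smallest median absolute difference between 2 arrays being 0.089, and 0 columns came from outside the series.

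Means of the 4 groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) to all 16 arrays at once, which left 12 residual degrees of freedom and gave 4.01 prior degrees of freedom. Evi1 siRNA was compared with control siRNA, Flag-Evi1 with Flag vector and control siRNA with Flag vector, 2-sided, with Benjamini-Hochberg adjustment over the 21062 probe sets and a threshold of 0.05. The difference of the first 2 comparisons was tested as a contrast, and the overlap of their calls was set against independent lists. Errors of differences are standard errors from limma, and errors of group means are SD. For MECOM and for the mean of the interferon list an exact 2-sided permutation test of the 4 against 4 arrays stands beside limma, and it cannot go below 0.0286.

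Passage number did not pair the arrays evenly. Across probe sets, the deviations of same-passage arrays from their group means correlated at passages 8 to 11 by 0.128, -0.00486, 0.00669 and 0.160 for the siRNA groups. For the plasmid groups they correlated by -0.0547, -0.0172, -0.0647 and 0.303, and for the control groups by 0.154, 0.00401, 0.0444 and 0.229. The array of the same passage was the closest of the other group in 2, 1 and 3 of 4 cases. The fit used group alone, and passage as a block was an alternative.

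The choices in this paragraph were made before the data were examined. The genes that could be named were chosen by rule: MECOM and PRDM16, and the 12 with the largest rise and the 12 with the largest fall (6 each between the control groups) among probe sets of 1 gene past the threshold and changed the same way in all 4 passages. Directions with fewer than 6 such genes were filled to 6 by the smallest unadjusted p, and up to 4 members per list with the smallest unadjusted p were added. Genes of opposite change were ordered by the larger p of the 2 comparisons and filled to 5. Gene lists were fixed from general knowledge: 34 lists with 894 genes, of which 810 were measured, each gene taken by its brightest probe set. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Alternatives were a block for passage, a fit of the compared groups alone, all probe sets or only those of 1 gene, leaving out dim probe sets (mean below 5.65), quantile normalization, centring on the array median, eBayes with trend and robust settings, array weights, a plain unmoderated test, other thresholds, the mean of a gene's probe sets for lists, and leaving out each array and each passage. A block for slide or scan date was planned only if the files gave one and was not run.

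The pipeline was tested on simulated data with 200 of 21062 probe sets changed. For Evi1 siRNA against control siRNA it recovered 31.3%, 77.6% and 100% of changes of 0.3, 0.5 and 1 (log2), for Flag-Evi1 against Flag vector 23.9%, 62.7% and 97.0%, and for control siRNA against Flag vector 32.8%, 70.1% and 97.0%. False calls were 1.42%, 4.69% and 6.99% of calls. A list shifted by 0.3 was called, and 0 of the other lists were. The simulated noise was independent between probe sets, so false list calls from genes that vary together were not tested. For arrays the number of arrays limits the precision. Dixon's ratio (above 0.829 for 4 arrays) marked arrays far from their group. Probe sets without a gene were left out of the comparisons and counted apart.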

Results

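EVI1 is a zinc-finger transcription factor encoded by the MECOM locus on chromosome 3. Its level was lowered or raised in SKOV-3, an established human ovarian carcinoma cell line, and RNA was collected 65 h after transfection. Expression was measured on 16 single-colour Affymetrix arrays that fall into 4 groups of 4. The groups received the empty Flag vector, a Flag-Evi1 plasmid, a non-targeting control siRNA pool or a pool of 2 siRNAs against Evi1. The 4 arrays of a group came from cell passages 8, 9, 10 and 11, so the spread within a group is that between passages of 1 cell line. The median log2 signal per array lay between 6.65 and 6.78, and the number of arrays limits the precision of every value.

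The second principal component, with 18.4% of the variance, placed the 4 Evi1 siRNA arrays between -17.8 and -13.5 and the other 12 arrays between 1.28 and 10.2. The first component, with 30.5% of the variance, set apart the passage 8 arrays of Flag vector at -34.0 and of Evi1 siRNA at -21.2, while the other 14 arrays lay between -7.90 and 17.6. The interquartile range of the log2 signal was 3.13 in that Flag vector array and 3.16 in that Evi1 siRNA array, against 3.26 to 3.45 in the other 14.

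**Figure D1:**
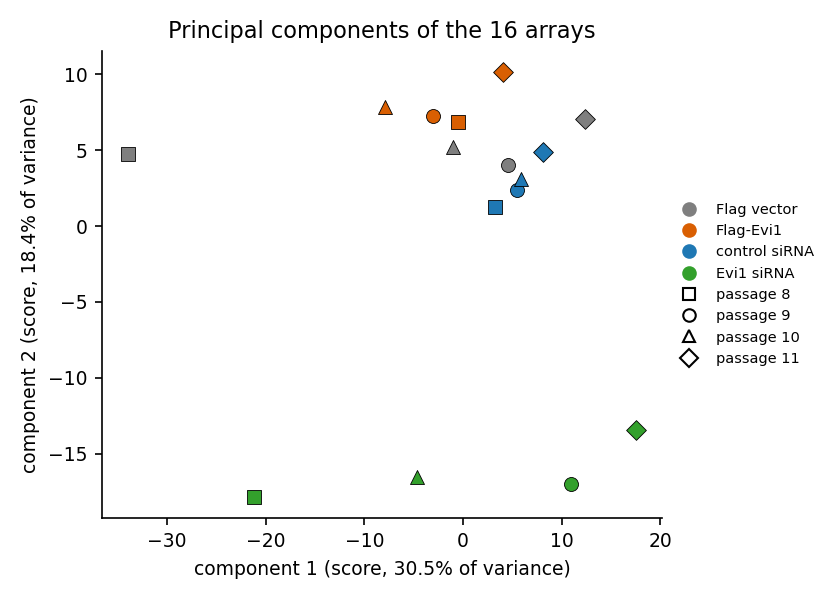
Scores of the 16 arrays on the first component (30.5% of the variance) and the second (18.4%), coloured by group with a marker per passage. The 4 Evi1 siRNA arrays lie below -13 on the second component, and the passage 8 arrays of Flag vector and Evi1 siRNA lie at -34.0 and -21.2 on the first.

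MECOM itself moved as each treatment was designed to move it. The brighter of its 2 probe sets, 8091972, read 11.58 ± 0.11 (SD, n = 4, log2) with control siRNA and 10.12 ± 0.28 with Evi1 siRNA, where it ranged from 9.91 to 10.54. It fell by 1.46 (SE 0.12, limma adjusted p = 2.95e-06), which left 36.4% of the control signal. With the Flag vector it read 11.47 ± 0.18 and with Flag-Evi1 13.14 ± 0.12, a rise of 1.67 (SE 0.12, limma adjusted p = 5.97e-06) or 3.19-fold. In both comparisons the 4 treated arrays lay wholly to 1 side of the 4 controls, with an exact 2-sided permutation p of 0.0286, the smallest that 4 against 4 allows. The other MECOM probe set, 8091991, fell by 0.56 with Evi1 siRNA (SE 0.12, limma adjusted p = 0.00929) and differed by 0.06 with Flag-Evi1 (SE 0.12, limma adjusted p = 1.0), below the spread between replicates. Its fall had an adjusted p of 0.0741 without passage 9 and of 0.121 without passage 10. MECOM spans positions 169083507 to 169663712 of chromosome 3 in GRCh38.p14. Its closest paralogue PRDM16, at 3069203 to 3438621 on chromosome 1, differed by 0.06 with Evi1 siRNA (adjusted p = 0.842) and by -0.04 with Flag-Evi1 (adjusted p = 1.0).

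**Figure D2:**
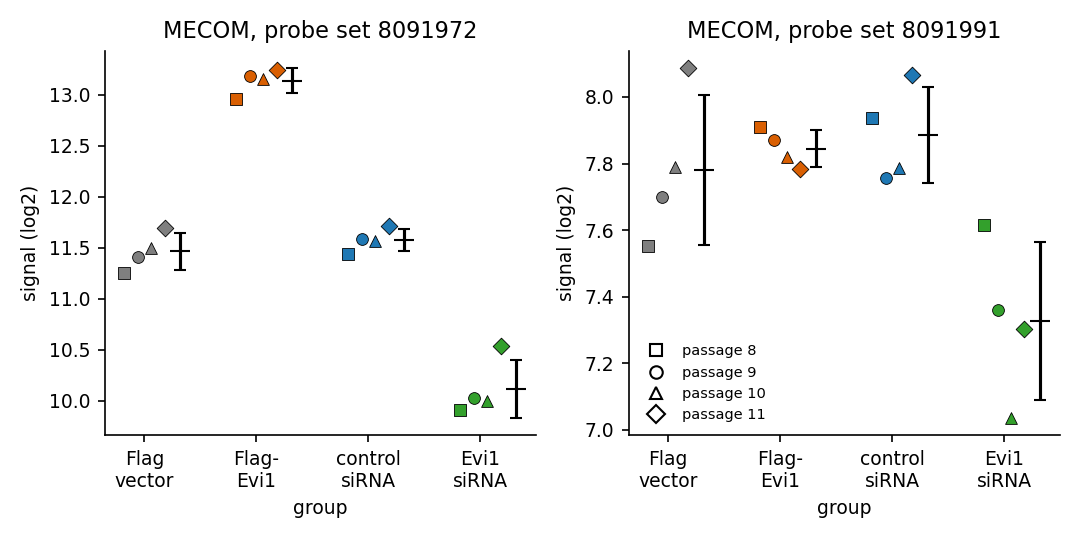
Log2 signal of the 2 MECOM probe sets in each of the 16 arrays, with group means and SD (n = 4) beside the points. With Evi1 siRNA probe set 8091972 lies between 9.91 and 10.54, below all control siRNA arrays, and with Flag-Evi1 it lies near 13.14.

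With Evi1 siRNA against control siRNA, the matrix protease MMP3 rose by 1.33 (log2, SE 0.10), the carboxypeptidase CPA4 by 1.53 (SE 0.14), the actin-like ACTBL2 by 1.63 (SE 0.15) and the secreted chaperone CLU by 1.16 (SE 0.09). Beside them rose the drug-metabolising cytochrome CYP3A5 (1.39), the opiorphin precursor OPRPN (1.36), the long noncoding RNAs UCA1 (1.34) and LINC01559 (1.01), the glycogen-targeting phosphatase subunit PPP1R3C (1.06), the dehydrogenase DHRS2 (1.05), the tryptophan-degrading enzyme KMO (1.02) and the serum- and glucocorticoid-regulated kinase SGK1 (0.98). After MECOM, the largest falls were those of the microtubule-binding MAP2 (-1.26, SE 0.15), the netrin NTNG1 (-1.03, SE 0.08), the kinase SGK2 (-0.996) and the integrin subunit ITGB3 (-0.98, SE 0.10). The laminin chain LAMA4 (-0.97), the matrix protein periostin POSTN (-0.96), the secreted protease inhibitor SLPI (-0.95), the interferon-inducible GTPase GBP5 (-0.93), RASSF9 (-0.93), the cholesterol ester hydrolase NCEH1 (-0.93, SE 0.06) and the secreted Wnt antagonist SFRP1 (-0.92) followed. These 24 genes, MECOM included, had the largest changes among the probe sets that the naming rule admits. They changed the same way in 4 of 4 passages, with limma adjusted p from 1.23e-07 to 0.00539 and SE from 0.06 to 0.24. Without passage 10 the adjusted p was 0.0641 for OPRPN, 0.0918 for RASSF9 and 0.0730 for SFRP1, and for SFRP1 it was 0.0512 without passage 9.

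**Figure D3:**
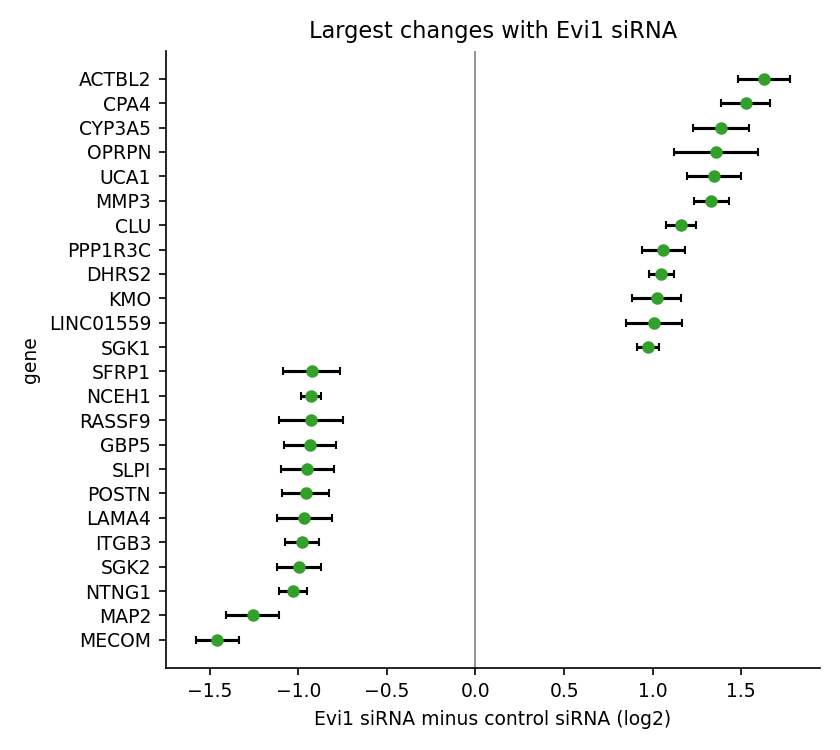
Difference of the means of 4 Evi1 siRNA and 4 control siRNA arrays (log2) for the 12 genes with the largest rise and the 12 with the largest fall, with bars of 1 SE from limma. The ranking is among probe sets of 1 gene past the threshold and changed the same way in all 4 passages. Of the genes shown, ACTBL2 has the largest rise (1.63) and MECOM the largest fall (-1.46).

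Histone and cytokine genes lay higher with Evi1 siRNA. Of 27 measured replication-dependent histone genes, which package newly made DNA, 9 rose and 1 fell, and 14 rose and 1 fell when adjusted over the list alone. Their median was 0.21 (camera adjusted p = 3.8e-08; adjusted p = 0.065 with an estimated correlation), and H1-1 (0.45), H4C4 (0.45), H3C8 (0.38) and H1-3 (0.32) are examples. Of 29 genes of inflammatory cytokines and the NF-kB pathway, 5 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (median 0.16, camera adjusted p = 0.00013; adjusted p = 0.46 with an estimated correlation). Among them the neutrophil chemokines CXCL1 and CXCL2 rose by 0.65 and 0.53 and TNFAIP2 by 0.40, while the receptor-associated kinase IRAK2 fell by 0.29. Of 19 AP-1 and immediate early genes 4 rose, and 5 rose and 1 fell when adjusted over the list alone. These were KLF4 (0.74), JUN (0.54), MYC (0.39) and KLF6 (0.31). The list had a camera adjusted p of 0.048, which was 0.20 with an estimated correlation and 0.121 with passage as a block. Without passages 8, 10 and 11 it was 0.0604, 0.0770 and 0.123, with the mean of probe sets 0.0503, without dim members 0.0562 and with array SD as a covariate 0.0704. Of 37 mitotic genes limma called 0, also when adjusted over the list alone, and 5 lay at an unadjusted p below 0.05 (median 0.02, camera adjusted p = 0.48). Of 40 DNA replication genes 1 rose, the origin recognition subunit ORC6 (0.22), and 0 when adjusted over the list alone (median 0.06, camera adjusted p = 0.083). Camera called this list with quantile normalization and without passage 8. ORC6 lost its call without any 1 of 7 of the 8 siRNA arrays, with adjusted p from 0.0636 to 0.143, and kept it without the Evi1 siRNA array of passage 11. Without passage 9 and without passage 10 the adjusted p was 0.0811 and 0.139 for H4C4, 0.0839 and 0.0940 for H1-3, 0.0507 and 0.0698 for MYC, 0.0933 and 0.173 for KLF6 and 0.140 and 0.0765 for TNFAIP2. Without passage 10 it was 0.0501 for H3C8 and 0.167 for IRAK2, without passage 8 it was 0.0614 for IRAK2, and without passage 11 it was 0.0648 for TNFAIP2.

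The lists of adhesion, Wnt and Notch, fibroblast marker, autophagy and lysosome, and unfolded protein response genes lay lower with Evi1 siRNA than with control siRNA. Their medians for control siRNA over Flag vector were 0.08, -0.03, 0.08, 0.11 and 0.01 in that order. Camera called the adhesion list and the autophagy and lysosome list there, both higher. For these, a high level in control siRNA was not told apart from a fall with Evi1 siRNA. Of 30 cell adhesion genes 5 fell and 3 rose, and 9 fell and 4 rose when adjusted over the list alone (median -0.12, camera adjusted p = 0.048; adjusted p = 0.91 with an estimated correlation). The semaphorin co-receptor NRP2 fell by 0.50 and the neural adhesion molecule L1CAM by 0.59 along with ITGB3, whereas the cadherin CDH6 rose by 0.93. Of 26 Wnt and Notch genes 6 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone (median -0.04, camera adjusted p = 0.021; adjusted p = 0.20 with an estimated correlation). The ligand WNT7A fell by 0.58 and the Notch-induced repressors HEY1 and HES1 by 0.45 and 0.37, in 1 list with SFRP1, which antagonises Wnt. Of 12 fibroblast marker genes, 8 of which read above 5.65 with control siRNA, the level under which a probe set was taken as dim, POSTN and FBLN1 (-0.28) fell, and 4 fell when adjusted over the list alone (median -0.14, camera adjusted p = 0.048; adjusted p = 0.46 with an estimated correlation). Of 24 autophagy and lysosome genes 3 fell, and 7 fell when adjusted over the list alone (median -0.10, camera adjusted p = 0.0067; adjusted p = 0.91 with an estimated correlation). The autophagy conjugation gene ATG12 (-0.36) was 1 of them, the others being ATG7 and the lysosomal protease CTSD. ATG7 and CTSD lost their calls when any 1 of several arrays was left out. Without the Evi1 siRNA array of passage 8, for example, the adjusted p was 0.0875 for ATG7 and 0.0984 for CTSD. Of 24 unfolded protein response genes 3 fell and 2 rose, and 6 fell and 2 rose when adjusted over the list alone (median -0.11, camera adjusted p = 0.021; adjusted p = 0.47 with an estimated correlation). The stress transcription factor XBP1 fell by 0.37 and the disulfide isomerase PDIA4 by 0.29. Without passage 9 and without passage 10 the adjusted p was 0.0525 and 0.0755 for L1CAM, 0.0546 and 0.101 for HES1, 0.0690 and 0.138 for FBLN1, 0.121 and 0.192 for ATG12 and 0.0957 and 0.186 for PDIA4. The fibroblast list missed the threshold without passages 9, 10 and 11 (camera adjusted p 0.162, 0.0506 and 0.152), with the mean of probe sets (0.0530) and with array SD as a covariate (0.0704). The adhesion list missed it without passages 8, 9 and 10 (0.0623, 0.0510 and 0.139), with each array centred on its median (0.0695), with the mean of probe sets (0.0503), without dim members (0.0761) and with the covariate (0.0704), and the unfolded protein response list without passage 10 (0.0506).

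Genes tied to EVI1 in earlier work, and genes of epithelial or mesenchymal identity, changed singly but did not pass as lists. Of 22 genes named in the literature as EVI1 targets, MYC rose, and the kinase MAP3K14 (-0.30) and the adhesion receptor ADGRG1 (-0.26) fell, while 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.87). Leaving out 1 array ended the call of ADGRG1 in 7 of 8 cases, with adjusted p from 0.0552 to 0.139. Of 18 described EVI1 partner genes limma called 0, also when adjusted over the list alone, with 3 at an unadjusted p below 0.05 (camera adjusted p = 0.85). Of 32 TGF-beta response genes 2 rose and 1 fell, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.85), and the feedback inhibitor PMEPA1 fell by 0.55. Of 25 epithelial genes 3 rose and 2 fell, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.84), with the claudin CLDN1 at 0.82 and the keratin KRT19 at -0.59. Of 25 mesenchymal genes 2 rose and 3 fell, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.86), with the cadherin CDH2 at 0.37 and the tropomyosin TPM2 at -0.53. Of 28 extracellular proteases and their regulators 4 rose and 4 fell, or 6 and 7 when adjusted over the list alone (camera adjusted p = 0.87). The inhibitor SERPINE2 rose by 0.67 in this list, and the sheddase ADAM10 (-0.51) and the urokinase receptor PLAUR (-0.37) fell. Of 30 kinase feedback genes 3 rose and 8 fell, as they did when adjusted over the list alone, including the phosphatase DUSP4 (0.70), IGFBP3 (-0.49) and ETV5 (-0.47), with a camera adjusted p of 0.097, or 0.0329 with passage as a block. Of 21 metallothionein and oxidative stress genes 7 rose and 3 fell, or 9 and 3 when adjusted over the list alone, with MT2A (0.61), MT1G (0.61), AKR1C3 (-0.39) and the cystine transporter SLC7A11 (-0.49) among them, at a camera adjusted p of 0.072, or 0.0329 with passage as a block. The microRNA-processing enzyme DICER1 fell by 0.40. PMEPA1, PLAUR, ADGRG1 and DICER1 were also called between the control groups, in the opposite direction. Without passages 8, 9 and 10 in turn the adjusted p was 0.0523, 0.0578 and 0.165 for MAP3K14, without passages 9 and 10 it was 0.0636 and 0.0961 for ETV5 and 0.0507 and 0.0698 for MYC, and without passage 10 it was 0.0636 for IGFBP3.

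In all, 1123 of 21062 probe sets with a gene passed the limma adjusted p threshold of 0.05 with Evi1 siRNA, 440 higher and 683 lower (39.2% higher), for 1048 distinct genes. Chance alone would give 1053.1 at an unadjusted p below 0.05, where 3399 were found. Of those past the adjusted threshold, 156 changed at least 1.5-fold and 16 at least 2-fold, 13 of these higher and 3 lower, and the median absolute change was 0.36. Camera called 9 of the 34 lists, the pair of MECOM and PRDM16 among them, which MECOM carries by design. With an estimated correlation 0 of the 9 held. By contrast fry, which asks whether a list moves on balance without comparing it with other genes, called 7, that pair among them. The median, mean and test differed in sign in 5 lists here, in 7 with Flag-Evi1 and in 5 between the control groups, all of them uncalled. With each array centred on its median 219 were higher and 510 lower (30.0% higher), and without the Evi1 siRNA array of passage 11, 405 and 1003 (28.8% higher). The count of probe sets fell to 699 without the control siRNA array of passage 10, to 330 without passage 9 and to 281 without passage 10. Of the 71 called genes named here, 20 lost their call without passage 9 and 25 without passage 10. Without the passage 8 arrays of Flag vector and Evi1 siRNA that stood apart it was 1379, with 699 higher and 680 lower, and the lists of AP-1, autophagy and lysosome, adhesion, MECOM with PRDM16 and unfolded protein response genes then missed the threshold (adjusted p 0.0613 to 0.171).

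With Flag-Evi1 against Flag vector, interferon-response genes rose and of the other genes MECOM alone passed. The antiviral GTPase MX1 rose by 1.91 (log2, SE 0.15, limma adjusted p = 7.37e-06), more than MECOM itself. The oligoadenylate synthetases OAS1 and OAS2 rose by 1.48 (SE 0.15) and 1.45 (SE 0.16), IFI44L by 1.55 (SE 0.22), IFI6 by 1.35 (SE 0.12) and IFI27 by 1.06 (SE 0.13). IFIT1 (1.05), XAF1 (0.97), the interferon signalling factor IRF9 (0.80), the viral tether BST2 (0.74) and the RNA sensor IFIH1 (0.70) made up the rest. Together with MECOM these 12 genes were all that passed, 12 of them higher and 0 lower, each in 4 of 4 passages. In the other direction limma called 0 genes, with 316 probe sets lower at an unadjusted p below 0.05, and the smallest unadjusted p values belonged to GCSAM (-0.35, adjusted p = 0.459) and GNB3 (-0.29, adjusted p = 0.734). In both directions 651 probe sets lay at an unadjusted p below 0.05, fewer than the 1053.1 that chance gives.

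Of 41 measured interferon-response genes 11 rose and 0 fell over all genes tested, and 31 rose and 0 fell when adjusted over the list alone. Of the 41, 37 lay above 0, with a median of 0.48 (camera adjusted p = 6.2e-78; adjusted p = 0.0017 with an estimated correlation). The mean over the list differed by 0.58 between the groups (exact 2-sided permutation p = 0.0286, the smallest possible for 4 against 4 arrays). IFIT3 (0.77), IFIT2 (0.97), RSAD2 (0.71) and ISG15 (0.37) were past the threshold only when adjusted over the list alone. The interferon genes IFNB1 (-0.22) and IFNL1 (0.04) themselves passed neither. Of 30 oxidative phosphorylation genes limma called 0, over all genes or adjusted over the list alone, 4 were higher at an unadjusted p below 0.05, and 23 lay above 0 (median 0.08, camera adjusted p = 6.1e-06; adjusted p = 0.51 with an estimated correlation). Camera also called histone (median 0.03), unfolded protein response (0.03), kinase feedback (-0.02) and mitotic genes (-0.03) with adjusted p from 0.027 to 0.041. Limma called 0 members of these 4 lists, over all genes or adjusted over the list alone, with 3, 3, 1 and 0 members at an unadjusted p below 0.05, and their adjusted p was 0.54 to 0.97 with an estimated correlation. Of the 7 lists called, interferon response and the pair of MECOM and PRDM16 held with an estimated correlation, and fry called the same 2. The call of the pair comes from MECOM, which the treatment raises by design. Interferon response was thus the only list without MECOM that held. The unfolded protein response list had an adjusted p of 0.0642 with passage as a block, and without the 2 passage 8 arrays that stood apart it reached 0.0777 and the histones 0.293. Without passages 9, 10 and 11 in turn the adjusted p was 0.234, 0.198 and 0.352 for kinase feedback genes, 0.581, 0.470 and 0.505 for mitotic genes and 0.234, 0.115 and 0.221 for unfolded protein response genes. Without passage 8 it was 0.0503 for unfolded protein response genes and 0.577 for histones. With quantile normalization those 2 lists were at 0.175 and 0.0829, and with each array centred on its median kinase feedback and mitotic genes were at 0.0598 and 0.206.

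**Figure D4:**
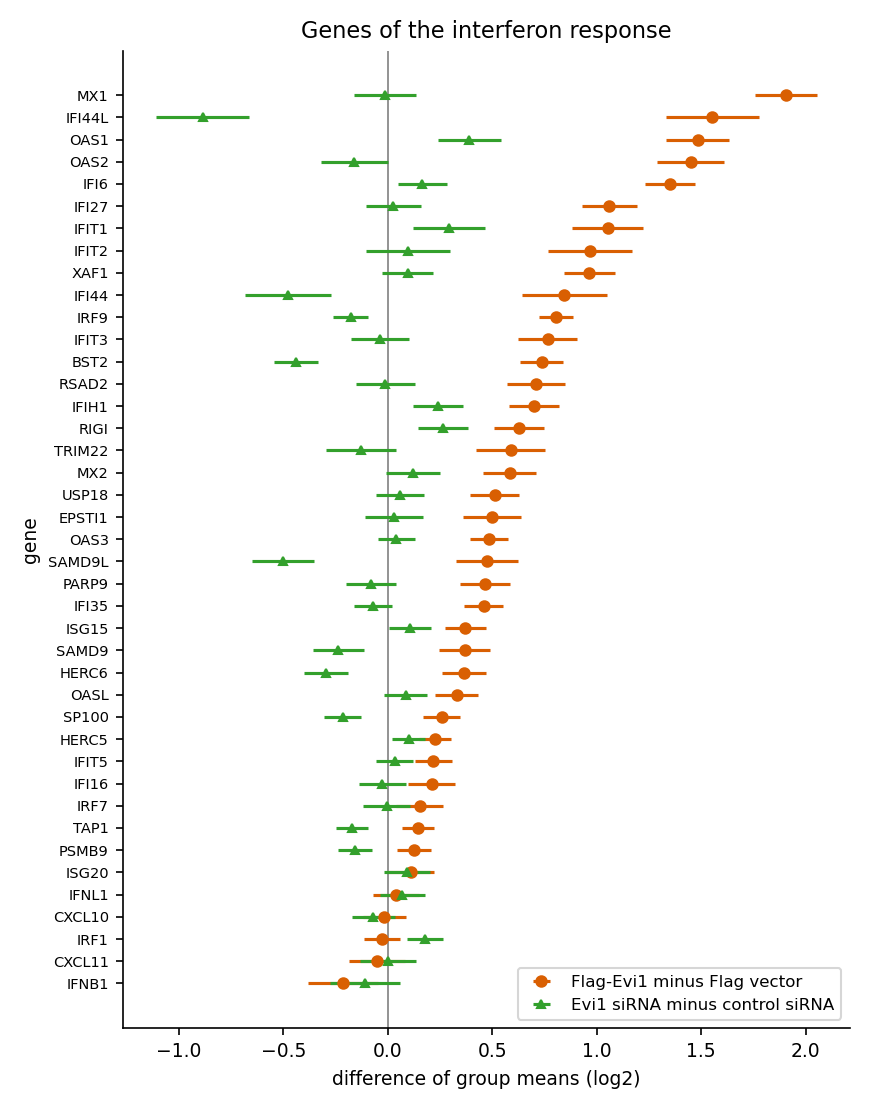
Difference of group means (log2, bars of 1 SE from limma, n = 4 per group) for the 41 measured interferon-response genes, with Flag-Evi1 against Flag vector as circles and Evi1 siRNA against control siRNA as triangles. With Flag-Evi1 37 of the 41 lie above 0, and with Evi1 siRNA 21 of the 41 lie below 0.

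The count of 12 was 25 probe sets with passage as a block, all 25 higher, and 5 without passage 9 (MECOM, MX1, OAS1, IFI6 and IRF9). Without passage 10 the adjusted p was 0.124 for IFI44L and 0.253 for BST2, and without passage 11 it was 0.0778 for BST2 and 0.0866 for IFI27. Single arrays decided IFIT1 and IFIH1: without the Flag-Evi1 array of passage 9 their adjusted p was 0.153 and 0.240, and leaving out the Flag vector arrays of passages 8, 9 or 10 ended both calls as well, as did the Flag-Evi1 arrays of passages 10 and 11 for IFIH1.

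Few genes answered to both treatments. MECOM fell and rose by design, BST2 changed by -0.44 with Evi1 siRNA and 0.74 with Flag-Evi1, and IFI44L by -0.89 and 1.55. These 3 genes were past the limma threshold in both comparisons in opposite directions, but the treatments fix the direction of MECOM. Without it 2 genes remained, where independent lists would share 0.356 (Fisher's exact test, 2-sided p = 0.0473, MECOM left out), and interferon-response genes are not independent of each other. In the same direction limma called 0 in both, where 0.251 would be shared by chance, and 34 lay at an unadjusted p below 0.05 in both, against 104 in opposite directions. The passage 8 arrays of Evi1 siRNA and Flag vector deviated together and enter the 2 comparisons with opposite sign, which favours opposite changes. Without them the count of 3 genes was 2, BST2 and MECOM, and IFI44L lost its call with Evi1 siRNA. The counts of 34 and 104 were not repeated without them. Next among genes of opposite change came the prostaglandin synthase PTGS1 (-0.39 and 0.26) and the lysosomal thiol reductase IFI30 (-0.44 and 0.38). Their limma adjusted p was 0.186 and 0.266 in the Flag-Evi1 comparison. With Evi1 siRNA the interferon-response list had a median of -0.01 (camera adjusted p = 0.65), with BST2 and IFI44L its 2 called members over all genes and adjusted over the list alone. With passage as a block the count was 6, adding IFI30, IFI44 and IFITM1. Both siRNA calls were lost when any 1 of several arrays was left out. Without the Evi1 siRNA array of passage 8 BST2 had an adjusted p of 0.0609 and IFI44L of 0.0690. Leaving out the Evi1 siRNA array of passage 9 or 10 ended both calls too, and each of these cases left a count of 1. Without the control siRNA array of passage 10 the call of BST2 ended. Without that of passage 9 or 11 the call of IFI44L ended, and each of these left a count of 2. With Flag-Evi1 the call of BST2 ended without passage 9, 10 or 11 (adjusted p 0.635, 0.253 and 0.0778) and that of IFI44L without passage 9 or 10 (0.380 and 0.124).

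Across 21062 probe sets the 2 sets of log2 ratios had a Pearson r of -0.13 and a Spearman rho of -0.13, and genes are not independent replicates. Without single arrays that r lay between -0.01 (Flag vector at passage 8) and -0.18 (Flag vector at passage 11), with -0.08 without the Evi1 siRNA array of passage 8 or the Flag-Evi1 array of passage 11. Without both passage 8 arrays that stood apart it was -0.14, without passage 9 or passage 11 -0.19, and with array weights -0.04. Among the 1121 probe sets called with Evi1 siRNA, MECOM left out, 61.5% moved in opposite directions (r = -0.27), and without the 2 passage 8 arrays that stood apart 52.6% did (r = -0.17). The limma test of the difference between the 2 responses called 436 probe sets, 169 with a higher and 267 with a lower response to Evi1 siRNA. That count was 814 with passage as a block, 263 with each array centred on its median, 953 with array weights, 996 with array SD as a covariate, 1173 with block and covariate, 742 without the 2 passage 8 arrays that stood apart, 284 without the control siRNA array of passage 10, 668 without the Evi1 siRNA array of passage 11, 42 without passage 9 and 38 without passage 10.

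The control groups differ in the nucleic acid delivered, and comparing them shows how far the 2 kinds of transfection differ without a designed change of EVI1. Relative to Flag vector, control siRNA cells had more of the enamel-type matrix protein AMTN (1.27, SE 0.18), GLIPR1 (1.17, SE 0.15), the actin-bundling LCP1 (0.92), NREP (0.71) and SEL1L3 (0.70). They had less of the Wnt antagonist DKK1 (-0.84, SE 0.10), the granule proteoglycan SRGN (-0.69), the retrotransposon-derived PEG10 (-0.66), ZBED2 (-0.57) and the vasoconstrictor EDN1 (-0.56), each in 4 of 4 passages. Of 28 extracellular proteases and their regulators 4 rose and 0 fell, and 8 rose when adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.49 with an estimated correlation), with PLAUR (0.38), PLAU (0.30) and ADAM19 (0.51) among them. Of 30 adhesion genes 3 rose, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.2e-05; adjusted p = 0.56 with an estimated correlation), with the integrin subunits ITGA5 (0.54) and ITGB6 (0.56) among them. Of 25 mesenchymal genes the gelatinase MMP2 rose by 0.69 and 3 rose when adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.24 with an estimated correlation). Of 24 autophagy and lysosome genes 22 lay above 0 and limma called 0, with 7 higher at an unadjusted p below 0.05 and 1 when adjusted over the list alone (median 0.11, camera adjusted p = 4.5e-06; adjusted p = 0.56 with an estimated correlation). Of 37 mitotic genes 29 lay below 0 and limma called 0, also when adjusted over the list alone, with 9 lower at an unadjusted p below 0.05 (median -0.06, camera adjusted p = 0.00015; adjusted p = 0.56 with an estimated correlation). The RNA interference list, with DICER1 up by 0.35 as 1 called of 13 members and also 1 adjusted over the list alone, had a camera adjusted p of 0.041 (adjusted p = 0.73 with an estimated correlation), and 0.669 without the 2 passage 8 arrays that stood apart. Of the 22 reported EVI1 targets 17 lay below 0 (median -0.08, camera adjusted p = 0.045; adjusted p = 0.24 with an estimated correlation) while ADGRG1 rose by 0.55, 1 rose and 3 fell when adjusted over the list alone, and the adjusted p was 0.0537 without those 2 arrays. The interferon-response list had a median of 0.04 (camera adjusted p = 0.49), and epithelial genes had a camera adjusted p of 0.12, or 0.0271 with passage as a block. Without passages 9 and 10 the adjusted p was 0.0692 and 0.0678 for mesenchymal genes, without passages 8, 9 and 10 it was 0.0667, 0.0709 and 0.176 for reported EVI1 targets, and without passage 8 it was 0.476 for RNA interference genes. With quantile normalization these 3 lists had 0.0501, 0.0501 and 0.0727.

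In that comparison 115 of 21062 probe sets passed in limma, 83 higher and 32 lower, and 1903 lay at an unadjusted p below 0.05 against 1053.1 by chance. With each array centred on its median the split was 46 higher and 8 lower of 54, or 85.2% higher against 72.2%. Without the 2 passage 8 arrays that stood apart it was 74 higher and 60 lower of 134 (55.2% higher), and without the Flag vector array of passage 8 alone 50 higher and 38 lower of 88 (56.8% higher). With passage as a block 270 passed. Without passage 9 or without passage 10 limma called 0, with 1481 and 1142 at an unadjusted p below 0.05, and leaving out single arrays gave counts from 49 (either passage 10 array) to 88 (the Flag vector array of passage 8). In between, the count was 51 and 55 without the control siRNA arrays of passages 9 and 8, 59 without that of passage 11 and 63 without the Flag vector array of passage 9. PEG10, ZBED2, the small nucleolar RNA SNORD116-28 (0.69) and UCA1 (-0.71) each lost their call without some single arrays, for example without the Flag vector array of passage 10, where their adjusted p was 0.112, 0.0633, 0.152 and 0.152. With passage as a block SNORD116-28 had an adjusted p of 0.0544. Of the 7 lists called by camera, 0 held with an estimated correlation, and fry called 2.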

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

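Chosen only after the results were seen were the tests of spread between plasmid arrays, of signal range and of exchanged labels and the fits without the 2 passage 8 arrays.

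In groups of 4 arrays, the farthest array was compared with the range of its group for the genes, lists and array measures reported. Of 238 gene groups 8 exceeded the critical value, of 68 list groups 6 and of 20 array-measure groups 1, where chance marks about 1 in 20. The SD of the log2 signal in the Flag vector array of passage 8 gave a gap of 0.916 of the range. Among genes the ratio was 0.982 for SLPI in Evi1 siRNA at passage 11, 0.949 for PRDM16 in Flag-Evi1 at passage 8, 0.917 for HES1 in control siRNA at passage 9, 0.903 for ITGB6 in Flag vector at passage 8 and 0.864 for RSAD2 in Flag-Evi1 at passage 8. It was 0.853 for JUN in Evi1 siRNA at passage 9, 0.835 for IFNB1 in Flag vector at passage 10 and 0.830 for PLAU in Flag vector at passage 11. Among list means it was 0.917 for MECOM with PRDM16 in Flag vector at passage 9, 0.911 for RNA interference genes and 0.873 for autophagy and lysosome genes in Flag vector at passage 8, and 0.907 for mesenchymal genes in Flag vector at passage 10. For kinase feedback genes in Flag-Evi1 and reported EVI1 targets in Evi1 siRNA, both at passage 11, it was 0.905 and 0.894. Of these 15 the Flag vector array of passage 8 accounted for 4. Outside the comparisons, 39 of 7807 probe sets without a gene passed with Evi1 siRNA, 26 higher and 13 lower, 3 between the controls, 1 higher and 2 lower, and limma called 0 with Flag-Evi1.

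Interferon-response genes rose with Flag-Evi1. A response to plasmid DNA as such would have raised them in Flag vector too. Their median for control siRNA over Flag vector was 0.0394 (list mean 0.04, exact permutation p = 0.286). Both control groups were transfected and no group was left untransfected. Similar levels in them could not tell no response from a similar response to plasmid and to siRNA, so this was not decided. A single array did not carry the rise, since the list difference of 0.58 was 0.49 without the Flag-Evi1 array of passage 11, the lowest without 1 array, or 0.853 of the whole. Whether the EVI1 level moves these genes both ways stayed open, because the list mean with Evi1 siRNA differed by -0.04 (exact permutation p = 0.4) and 21 of 41 members lay lower. Of the 11 members called with Flag-Evi1, 5 lay lower with Evi1 siRNA, and the median of the 11 there was 0.03. A difference in amount or purity between the 2 plasmid preparations was not tested, so that a response to EVI1 may be held only as a hypothesis.

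Far more probe sets changed with Evi1 siRNA (1123, for 1048 genes) than with Flag-Evi1 (12). A larger spread between plasmid arrays was argued against by the median within-group SD, which was 1.03 times as large in the plasmid groups (0.134 for Flag vector and 0.0850 for Flag-Evi1, against 0.0810 for control siRNA and 0.132 for Evi1 siRNA). If EVI1 moved the same genes both ways, the Flag-Evi1 ratios of probe sets called with Evi1 siRNA, signed by the siRNA change, would lie below 0. Their median was -0.0195, a value reached by 12 of 70 ordered splits of the plasmid arrays (lowest other -0.03), and -0.01 without the 2 passage 8 arrays, so this could not be told apart from no response. Effects of the siRNAs on other transcripts and a response already complete at the level of EVI1 in these cells were not tested and stay open.

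The passage 8 arrays of Flag vector and Evi1 siRNA stood apart together, with deviations that correlated by 0.702. A narrower signal range as the whole cause was argued against by quantile normalization, which gives all arrays 1 range and left that correlation at 0.647, against at most 0.443 (SD 0.158) among the 95 other pairs of arrays from different groups. In both arrays the deviation fell with signal level (Spearman rho -0.407 and -0.378). In the other arrays of these groups rho lay between -0.262 and 0.377. A narrower range as part of the cause thus stays open, and compression that differs between probe sets was not tested. An exchange of their 2 labels was argued against by MECOM, which lay 1.07 or more from the other array's group and 0.28 or less from its own. Cells of another type would have raised their markers in both arrays, and fibroblast, blood cell and endothelial markers were set against random lists. Fibroblast markers lay at percentiles 2.45 and 4.48 and were thus not raised. Each array was compared with later passages of its own group. COL1A1, 1 of the 12 markers, rose by 0.21 per passage also without these 2 arrays. A rise with passage would lower the percentiles, so fibroblasts were not excluded. Endothelial markers lay at 27.5 and 31.1. Blood cell markers deviated upward by 0.200 and 0.194, at percentiles 82.6 and 93.7, so blood cells were not excluded. Further cell types were not looked at. Other technical differences, such as RNA quality or the handling of the arrays, were not tested and stay open, and no biological explanation was tested, as the design gives none for these 2 arrays.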

How the results depend on the processing

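Leaving out the 2 passage 8 arrays and adding each array's SD as a covariate, with or without the passage block, were chosen after seeing the data. Of the alternatives, those that kept each result within 1.5 times or on its side of the threshold number 214 for counts, 3018 for genes chosen by rule and 240 for lists, whereas 153 counts moved further and 551 gene and 105 list calls were lost in the same direction. No gene or list called in the main fit turned its direction. Of the lists not called, 2 with Evi1 siRNA, 4 with Flag-Evi1 and 8 between the controls did so with quantile normalization or centring. The count of probe sets with Evi1 siRNA (1123) was 683 with the compared groups alone, 729 with arrays centred on the median, 1717 with array weights, 321 with a plain test, 156 at 1.5-fold, 508 at a threshold of 0.01, 2029 with the SD covariate, 2260 with covariate and block, and 281 to 1408 without single arrays or passages. The count with Flag-Evi1 (12) was 25 with the block, 5 with the compared groups alone, 23 with array weights, 0 with a plain test (744 at an unadjusted p below 0.05), 22 with the covariate, 28 with both, and 5 to 17 without arrays. Between the controls (115) it was 270 with the block, 20 with the groups alone, 176 with quantile normalization, 54 with centring, 191 with trend and robust settings, 331 with array weights, 13 with a plain test, 18 at 1.5-fold, 39 at 0.01, 192 at 0.1, 222 with the covariate, 273 with both, and 0 to 88 without arrays. Opposite change (3) gave 6 with the block, 1 with the groups alone, 0 with a plain test, 1 at 0.01, 5 with the covariate, 8 with both, and 1 to 4 without arrays. The count of different responses (436) was 179 at 1.5-fold, 166 at 0.01, 714 at 0.1 and 38 to 668 without arrays or passages.

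The brighter MECOM probe set differed by -1.598 to -1.39 with Evi1 siRNA and 1.602 to 1.75 with Flag-Evi1 without single arrays or passages, and passed the threshold in each of these fits, whereas the fall of the other did not without passage 9 or passage 10 (adjusted p 0.0741 and 0.121). With the plain test its Flag-Evi1 difference of 1.67 missed the threshold (adjusted p = 0.105). Lists called with Evi1 siRNA (9) were 5 with the mean of probe sets, 0 with an estimated correlation, 5 with the covariate and 6 to 11 without passages. With Flag-Evi1 (7) they were 2 with an estimated correlation, 2 with fry and 4 to 6 without passages. The 9 and the 7 include the pair of MECOM and PRDM16, which MECOM carries by design. Between the controls (7) they were 4 with quantile normalization, 0 with an estimated correlation, 2 with fry, 4 without dim members and 5 to 9 without passages. No called list turned direction with quantile normalization or centring.

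With passage as a block the counts were 1588, 25 and 270, and of the called genes that the comparisons name 71 of 71 with Evi1 siRNA, 12 of 12 with Flag-Evi1 and 19 of 20 between the controls kept their call. A stricter threshold lowers a count by construction, and for the other settings the cause was not tested. Array weights were lowest for Flag vector (0.200) and Evi1 siRNA (0.408) at passage 8. Evi1 siRNA at passage 11 came next (0.429), the array with the highest MECOM signal of its group (10.54, probe set 8091972). No detection limit was used here, and leaving out probe sets with a mean below 5.65 (16334 of 21062 remained) gave 1269, 13 and 154 probe sets. Signal over background was not measured, so which calls it limits was not tested. Background correction and a slide or date block could not be run on the table used here.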

Other observations

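The tests of a trend with passage and of the shared control siRNA arrays were chosen after the results were seen, as were the genes named in this part. In limma with passage as a trend and group as a covariate, the collagenase MMP1 rose by 0.40 per passage (log2), the matrix protein SPARC by 0.34, the collagens COL5A2 and COL1A1 by 0.23 and 0.21, and the desaturases SCD and FADS2 by 0.30 and 0.21. The YAP-responsive ANKRD1 (-0.29) and CCN2 (-0.16), the smooth muscle gene TAGLN (-0.22) and the cytokine IL1A (-0.26) fell. In all 757 probe sets passed, 609 higher and 148 lower. Without the 2 passage 8 arrays that stood apart 98 passed, 62 higher and 36 lower, and without passage 8 altogether 23, 16 higher and 7 lower. MMP1 (0.47), SPARC (0.29), COL5A2 (0.27), SCD (0.33), FADS2 (0.25) and ANKRD1 (-0.44) passed in that smaller set too. Passage and any order of processing could not be separated. These fits treated arrays of the same passage as independent, although every passage supplied an array to each group. A difference shared by the arrays of a passage thus counted once per array, so the counts may be too high. Whether the trends hold with the passage as the unit was not tested.

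Among the kinase feedback genes with Evi1 siRNA, ETV1 (-0.82, SE 0.19), DUSP6 (-0.72, SE 0.18), ETV4 (-0.41), SPRY4 (-0.40), SPRY1 (-0.39) and the receptor MET (-0.35) fell beside ETV5, whereas EGFR (0.32) and IGF1R (0.37) rose beside DUSP4. With IGFBP3 (-0.49) these are the 11 called of 30, and the list had a camera adjusted p of 0.097. Without 1 of the 8 siRNA arrays in turn, SPRY4 was called in 1 case, DUSP6 and SPRY1 in 3, ETV1 in 4 and ETV4 in 7 of 8. The highest adjusted p was 0.0850 for DUSP6, 0.116 for SPRY1 and 0.0692 for ETV1 without the control siRNA array of passage 11, and 0.128 for SPRY4 and 0.0521 for ETV4 without the Evi1 siRNA array of passage 8. The other 6 genes were called in all 8. Of these, IGF1R and ETV5 lost their call without passage 9 and without passage 10, and IGFBP3 without passage 10.

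Of 115 probe sets called between the controls, 39 (33.9%) were also called in the opposite direction with Evi1 siRNA, 29 of the 683 that fell and 10 of the 440 that rose. In the same direction 3 were higher in both and 4 lower in both. Independent lists would share 3.36 in opposite and 2.77 in the same directions. Examples of opposite calls are UCA1 (1.34 and -0.71), DKK1 (0.52 and -0.84), PMEPA1 (-0.55 and 0.54), DICER1 (-0.40 and 0.35) and PLAUR (-0.37 and 0.38). Over the 39, the median absolute difference was 0.409 with Evi1 siRNA and 0.420 between the controls. Between Evi1 siRNA and Flag vector it was 0.109. For these probe sets control siRNA stood apart from both, which choosing opposite calls favours. The control siRNA arrays enter both comparisons with opposite sign: r across genes was -0.354, simulations without any effect gave -0.500, and with the control siRNA arrays divided 2 and 2 between the comparisons r was -0.154, or -0.0863 also without the passage 8 arrays that stood apart. In the 6 divisions, where no array entered both comparisons, lists of the same sizes with the smallest p shared 26 to 39 probe sets in opposite and 7 to 10 in the same directions, and without those passage 8 arrays 24 to 41 and 8 to 12.

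Other splits of the arrays were run for each count. Of 35 splits of the 8 siRNA arrays 1, the real one, gave as many probe sets (1123, highest other 0). The same held with Flag-Evi1, with 1 of 35 (12, highest other 0), and between the controls, with 1 of 35 (115, highest other 2). The count of 12 includes MECOM, which the treatment raises by design. The real groups thus stood first, but 1 of 35 is the smallest share that these splits can give. They cannot exclude chance by themselves. At an unadjusted p below 0.05, 1 of 35 splits gave as many with Evi1 siRNA (3399, highest other 2606), 22 of 35 with Flag-Evi1 (651, highest other 2674) and 2 of 35 between the controls (1903, highest other 2007). For lists, 6 of 35 splits gave as many with Evi1 siRNA (9, highest other 11), 7 of 35 with Flag-Evi1 (7, highest other 11) and 11 of 35 between the controls (7, highest other 12), so chance cannot be excluded for the number of lists. The counts with Evi1 siRNA and with Flag-Evi1 include the pair of MECOM and PRDM16, which MECOM carries by design. Among the 8 splits that part all same-passage arrays, the highest other count of probe sets was 0 in each comparison, and 1, 2 and 1 of the 8 splits gave as many lists, the real one included, with highest others of 5, 7 and 6. For the difference of the responses 4 of 100 drawn splits gave as many (436, highest other 548). All 4 kept the real siRNA groups, as did 5 draws in all (415 to 548), and the other draws gave at most 3, so that count rests on the siRNA arrays.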
